A study of Drosophila melanogaster with 3 samples.

How the data were processed

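The data are chromatin immunoprecipitation sequencing (ChIP-seq) of a GFP-tagged form of the Drosophila melanogaster protein CG2678 in whole embryos of mixed sex collected from 0 to 24 h of age. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against GFP, in 3 biological replicates. There was 1 group of samples, so no treated group, second tissue or second age was compared, and the only comparison between samples was that of the replicates with each other.

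The deposited files used here were 5 peak lists in narrowPeak form on the dm6 assembly, per the file headers and the deposited file descriptions. Each replicate had a relaxed list of 30000 peaks called against a control library, a pooled list of 30000 peaks was called on the 3 replicates together, and a further list held 9459 peaks kept after thresholding on the irreproducible discovery rate (IDR), which measures how far peak ranks hold across replicates. These were called the IDR peaks. The aligner, the peak caller and their versions are not given in the sources used here, and the control library was not analysed here, so open chromatin and effects of the control were not separated from binding, at promoters as elsewhere. All 9459 IDR peaks were found in the pooled list, and they were the 9459 pooled peaks of highest signal, so they were called on pooled samples and not in each replicate separately. The relaxed lists stop at 30000 peaks, so they hold a fixed number of peaks rather than all peaks past a threshold. Peaks with several summits stand as several lines, so that the 9459 IDR summits lay in 9041 separate intervals.

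The signal value of each peak is the authors' score, as deposited, and was taken to scale with sequencing depth, so it was used only to rank peaks within a list. The deposited −log10 q-value had a common maximum within each list (4.30 in the pooled list), which 9987 pooled peaks and all IDR peaks shared, and it was not used to rank peaks. The summit is the deposited offset from the start of the peak. Read counts per sample are not given in the lists, so the depth of each replicate and the counting error of each peak are unknown, and the spread of the 3 replicates is the only error that can be given. P-values over peaks or genes treat each peak or gene as independent. They describe these lists and do not measure variation between batches of embryos.

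Gene models were those of Ensembl release 115 (BDGP 6.54) and the sequence was the RefSeq copy of the same assembly as dm6. Chromosome names of the lists, after removal of the prefix, matched the 6 arms 2L, 2R, 3L, 3R, 4 and X, and every peak lay within the arm lengths (for example 23513712 bp for 2L and 32079331 bp for 3R). Coordinates are 1-based. Transposable elements annotated as genes were kept apart from the other 18164 genes. Soft-masked bases are those in lower case in the RefSeq sequence, which covers interspersed and low-complexity repeats.

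A summit matched a replicate when it lay within 100 bp of a summit among the 9459 strongest peaks of that replicate. Matches were compared with 100 random placements of the summits on the same arm (one-sided permutation test). Each summit was assigned to the first of promoter (within 500 bp of any annotated transcription start site, TSS), 5' UTR, coding sequence, 3' UTR, intron, other exon or intergenic sequence, and the shares were compared with 1000 random placements on the same arm (two-sided permutation test). The smallest p these placements can give is 0.002, or 0.0099 with 100 one-sided placements. The number of summits on each arm and in pericentromeric sequence was compared with 1000 placements over all arms. Pericentromeric borders were approximate and were set at 22.0 Mb of 2L, 5.5 Mb of 2R, 23.0 Mb of 3L, 4.5 Mb of 3R and 22.0 Mb of X. The intervals of 5 piRNA source loci were approximate as well.

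For sequence content, 15 motifs and all 2080 words of 6 bp were scored as present or absent on either strand within 50 bp of the summit, and compared with a window of the same length centred 300 bp away, with an exact McNemar test. For genes, the number of members of 18 lists with an IDR summit within 500 bp of a TSS was compared with the other protein-coding genes, of 13945 in all, with the two-sided Fisher's exact test; 10 gene biotypes were compared with all other genes in the same way. Odds ratios had 0.5 added to each cell. Histone, ribosomal protein and receptor genes were taken by symbol pattern, and after the lists had been opened 3 genes that are not histones were dropped from the histone pattern and older symbols were matched to current ones; 4 symbols of 3 lists had no match. Median signals were compared by a permutation test with 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method within each family, and 0.05 was the threshold.

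Values in each replicate were computed from its own 9459 strongest peaks and are given as mean ± SD with n = 3. Named peaks were the 20 IDR peaks of highest signal matched in all 3 replicates, with the gene of the nearest TSS, the 3 strongest such peaks in pericentromeric sequence, the 3 members of each gene list with the strongest promoter peak (2 where the list's adjusted p was 0.05 or more; 1 of the 3 ribosomal protein genes is not reported here), and CG2678. Groups, tests, gene lists, motifs, regions, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other summit, TSS and window distances, the 4730 IDR peaks of higher signal, the peaks matched in all replicates or in each pair, positions matched on the GC content of 200 bp, the weakest or remaining pooled peaks as background, borders moved by 500 kb, the 5'-most TSS alone, a background of genes with a pooled promoter peak, and 25 kb around the tagged gene. Chosen after seeing the data were the strongest summit of each interval, positions outside soft-masked sequence, GC matching for repeats, and, for the word CACTGT, a window ending 5 bp further out and words outside repeats.

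The tests were first run on simulated peaks. With part of 9459 random summits moved onto promoters, so that 30.9% were expected there, 31.4% were counted, and with none moved 13.7% were counted against 13.6% expected. A word planted in random windows ranked first of the 2080 words, and no word was called when none was planted; with 1 planted, 18 words were called, the other 17 overlapping it by 4 or 5 bp, so counts of words exceed counts of separate sequences. Of 100 simulated sets of promoter peaks in which 60% of the 86 ribosomal protein genes had one, all 100 called that list. With the 23 muscle genes in its place, 84 of 100 did. Another list was called in 10 of the 200 runs. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.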

Results

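CG2678, also named kipferl, is a zinc finger protein known from Drosophila ovaries, where it directs the heterochromatin protein Rhino to piRNA source loci. The experiment asked where the GFP-tagged protein was enriched on the genome of whole embryos 0 to 24 h old, in 3 biological replicates. Each replicate list and the pooled list held 30000 peaks, and 9459 pooled peaks passed the authors' IDR threshold. The IDR peaks had a median width of 372 bp and signal values, which are the authors' own, from 236.7 to 19817 with a median of 520.5.

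The strongest peaks lay at promoters and in introns of euchromatic genes. Of the 20 IDR peaks of highest signal that were matched in all replicates, 13 were in promoters and 6 in introns. The first in rank was on chromosome 2L at 480337 to 481709 (dm6), with its summit at 481057 in an intron of ush, 1369 bp upstream of the TSS of cbt, which encodes a zinc finger transcription factor. It had a signal of 19817 and ranked 5, 1 and 6 in replicates 1, 2 and 3. The next was in an intron of CG11050 (2L, 6612305 to 6613056), with a signal of 19236 and ranks of 3, 2 and 3. Peaks at the promoters of Ugalt, a UDP-galactose transporter gene (X, 2703513 to 2704183), and CG14100 (3L, 19590317 to 19590892) followed, with summits 29 bp and 90 bp upstream of the TSS (coded as -29 and -90) and signals of 19140 and 18872.

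Among the rest of these 20 peaks, promoter summits belonged to mRpL41, a mitochondrial ribosomal protein gene, Art3, an arginine methyltransferase gene, the glycolytic gene Gapdh2, the Polycomb group gene ph-p, Fkbp14, px, CG18549, CG13390, CG1888, the mitochondrial exonuclease gene PNPase and Pdrg1. Their signals ran from 16671 at mRpL41 (2R, 15217494 to 15218104) to 11144 at Pdrg1 (2R, 9959635 to 9960185). Intronic summits lay within Trl, which encodes the GAGA factor (3L, 14759129 to 14760662, signal 15801), within the overlapping high mobility group genes HmgD and HmgZ, within Lk6, which encodes a kinase, and within CG32772. A summit in an exon of the long noncoding RNA gene lncRNA:Vinr, nearest the TSS of lncRNA:CR44619 (X, 12750700 to 12752679), had a signal of 17645. The lowest rank of any of the 20 peaks in a replicate was 31, for Pdrg1 in replicate 2.

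The replicates shared most of their strong peaks. A summit matched 77.8% of the IDR peaks in replicate 1, 86.9% in replicate 2 and 81.1% in replicate 3 (82.0% ± 4.61, SD, n = 3), and 5865 IDR peaks, or 62.0%, were matched in all 3. Random placements of the summits gave 0.757% on average and at most 0.973% (one-sided permutation p = 0.0099, the smallest 100 placements can give). Only 157 IDR peaks were matched in none. The IDR peaks were the strongest peaks called on these same replicates pooled, cut by the IDR threshold, so their matches are not independent of the replicates. Between pairs of the replicates' own lists, 72.9% of the strongest peaks were shared by replicates 1 and 2, 70.5% by 1 and 3 and 73.3% by 2 and 3, against at most 1.82% of random placements in any pair (permutation p = 0.0099 for each). Signal ranks of the IDR peaks correlated with Spearman's rho of 0.837, 0.849 and 0.870 for the same pairs, across peaks, which are not independent replicates.

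Summits were concentrated at promoters and nearly absent from coding sequence. Promoters held 3246 IDR summits, or 34.3%, against 13.6% of random placements, a 2.53-fold higher share. Coding sequence held 20 summits, or 0.211%, against 13.7% of random placements, and 3' UTRs held 1.10% against 4.44%. Introns held the largest share, 45.6%, only 1.15 times the random 39.8%, and intergenic sequence 17.5% against 27.2%. Each of these differences had a permutation p of 0.002 and an adjusted p of 0.0028. The share in 5' UTRs was 0.603% against 0.782% (adjusted permutation p = 0.049, and 0.0909 with only the strongest summit of each interval) and that in other exons was 0.655% against 0.559% (adjusted permutation p = 0.236). In the strongest peaks of the single replicates the promoter share was 36.7% ± 4.47 and the coding share 0.176% ± 0.0244 (SD, n = 3). Against the 9459 weakest pooled peaks, of which 15.7% were in promoters, 1.55% in coding sequence and 52.3% in introns, the promoter share remained 2.19 times higher and the coding share stayed lower, whereas the intron share was then lower, at 0.872 times that of the weak peaks (Fisher's exact p = 2.49e-20).

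**Figure D1:**
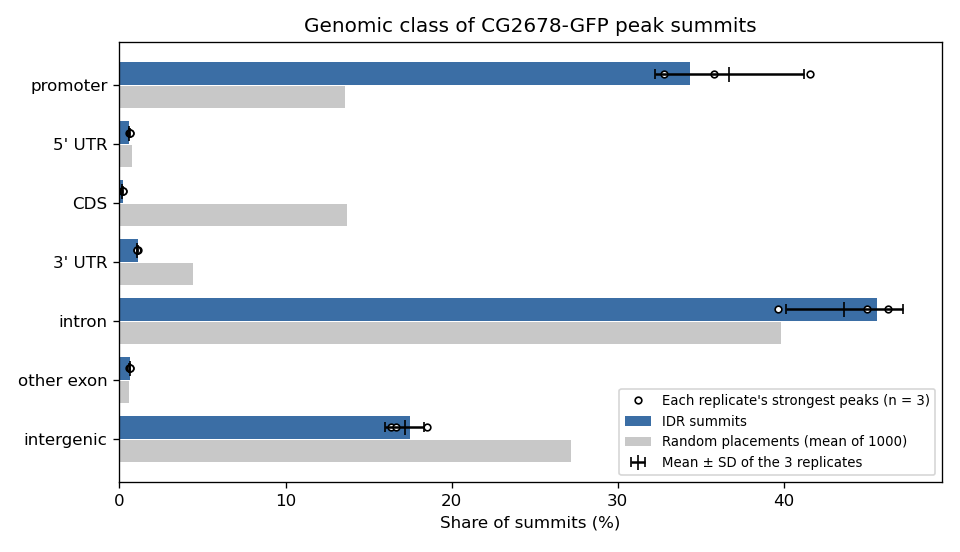
Share of summits (%, horizontal axis) in each genomic class for the 9459 IDR summits (blue bars) and the mean of 1000 random placements (grey bars); open circles are the strongest peaks of each of the 3 replicates, with their mean and SD. Promoters held 34.3% of IDR summits against 13.6% of random placements, and coding sequence 0.211% against 13.7%.

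Promoter summits lay mostly just upstream of the gene. Of those off the TSS itself, 2440 (75.3%, exact 95% interval 73.8 to 76.8) were upstream of the nearest TSS and 801 were downstream (exact binomial p = 1.31e-190). The test took equal shares as its null. Random placements were not scored for side, so the p does not measure an excess over them. The 50-bp bin with the most summits, 478, was from 150 to 100 bp upstream. Promoter peaks were also stronger than other IDR peaks, with a median signal of 613.9 against 487.0, a difference of 126.9 (two-sided permutation p = 2e-05, the smallest the resamples can give). Of the 946 IDR peaks of highest signal 56.3% were in promoters, of the 946 that followed 43.4%, and in each further set of that size between 28.0% and 34.2%.

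**Figure D2:**
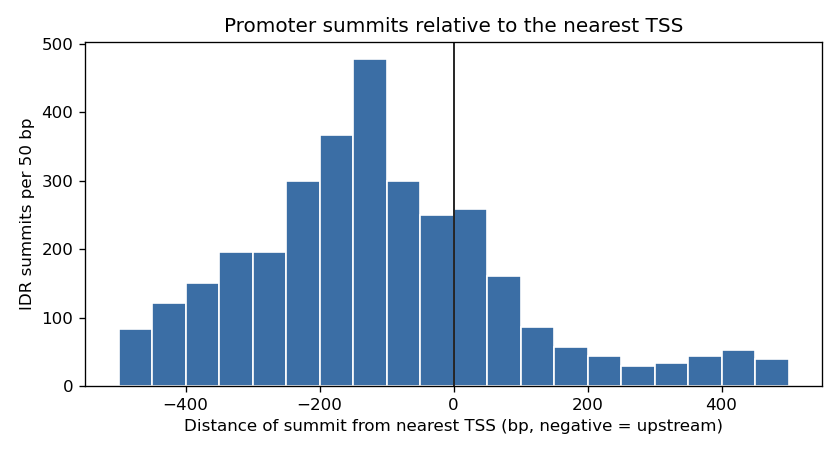
Number of IDR summits per 50-bp bin (vertical axis) by distance from the nearest TSS in bp (horizontal axis, negative values upstream), for the 3246 promoter summits. The highest bin, with 478 summits, lies 150 to 100 bp upstream, and 801 summits lie downstream.

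The summits were rich in A and T, and the G-rich sequence named for the protein in ovaries was scarce at them. GRGG (R is A or G) was present within 50 bp of 29.5% of IDR summits against 54.3% of flanking windows, a ratio of 0.544 (exact McNemar adjusted p = 4.15e-255). In the single replicates it was present at 30.5% ± 0.544 of summits and 53.7% ± 0.253 of flanks (SD, n = 3). Paired GRGG copies were present at 1.71% of summits against 7.75% of flanks. GC content averaged 32.4% at the summits and 43.8% in the flanks, and it was lower at the summit in 7557 of the 9459 peaks. At the 1000 strongest peaks it was 28.1% against 44.8%. Each of the 20 named peaks had a lower GC content at its summit than in its flanks, for example 19% against 44% at Fkbp14 and 22% against 46% at mRpL41. The 9459 weakest pooled peaks had 42.1% at the summit and 41.9% in the flanks.

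**Figure D3:**
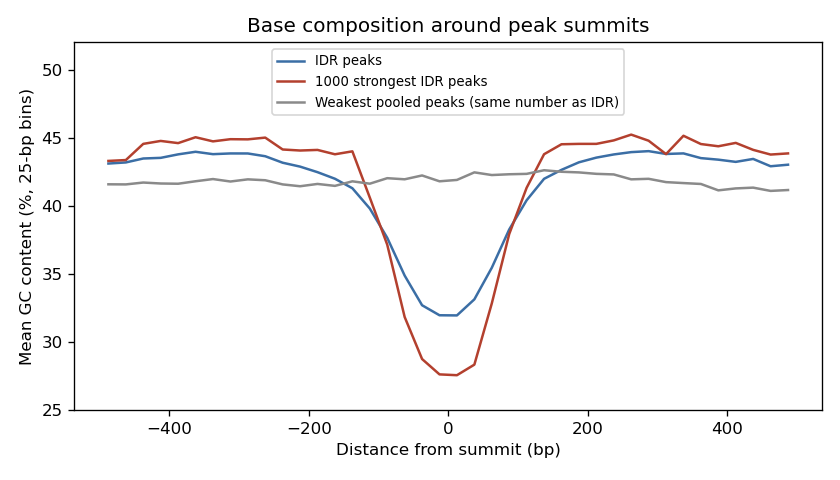
Mean GC content (%, vertical axis, 25-bp bins) by distance from the summit in bp (horizontal axis) for the 9459 IDR peaks, the 1000 strongest of them and the 9459 weakest pooled peaks. The IDR peaks average 32.4% within 50 bp of the summit and the 1000 strongest 28.1%, while the weakest pooled peaks average 42.1%.

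Of the 15 motifs, the TATA-box word TATAAA (24.9% against 9.82%, 2.54-fold), the A run AAAAAA (27.6% against 18.7%) and TATCGATA, bound by the promoter factor Dref (0.677% against 0.375%), were more frequent at summits than in flanks, with exact McNemar adjusted p of 4.47e-176, 1.58e-51 and 0.0117. Against positions of equal GC content TATAAA was 1.19 times as frequent and AAAAAA was no longer called (ratio 1.00, exact McNemar adjusted p = 1), and TATCGATA was not called in the 4730 stronger peaks (exact McNemar adjusted p = 0.398), in peaks matched in all replicates (0.137), without replicate 1 or 2 (0.254 and 0.0649) or within 25 bp (0.223). Less frequent were the GAGAG word of the GAGA factor (8.74% against 15.2%), the G run GGGG (15.4% against 32.8%), GCCAT, bound by Pho (12.7% against 19.0%), the CA repeat ACACAC (5.93% against 10.8%), CACGTG, CAGCTG, CGCGCG, paired GRGG and the initiator TCAGTT (8.74% against 9.74%, exact McNemar adjusted p = 0.0307, but 0.0557 to 0.0796 without each replicate). The Zelda word CAGGTA and the M1BP word GGTCACAC were not called against flanks (exact McNemar adjusted p = 0.511 and 0.916), but GGTCACAC was more frequent than at positions of equal GC content (0.486% against 0.148%, exact McNemar adjusted p = 0.000158) and CAGGTA was more frequent than in flanks at summits with no soft-masked base within 50 bp (ratio 1.68, exact McNemar adjusted p = 0.00267). Of all words of 6 bp, 551 were more frequent and 1172 less frequent at summits, and all 36 words made of A and T alone were among the former. AAATAT was at the head, in 37.1% of summits against 14.2% of flanks, and AGCAGC headed the latter, with 3.96% against 9.80%. Against positions of equal GC content, GRGG was still less frequent (34.7% at those positions, ratio 0.852), and 206 words were more and 360 less frequent. Of the motifs that were lower than in flanks only GRGG and GCCAT (adjusted exact McNemar p = 0.000148) were still called lower, while CGCGCG was called higher (ratio 2.19, adjusted exact McNemar p = 0.00263). These positions were matched on the GC content of 200 bp, while words were scored within 50 bp of the summit. GC content at IDR peaks was lowest within those 50 bp, so the scored windows of the matched positions may be richer in GC. A shortage of GRGG or GCCAT, or an excess of words rich in A and T, beyond base composition is therefore not shown. At summits with no soft-masked base within 50 bp GCCAT, CACGTG, CAGCTG and CGCGCG were no longer called lower than in flanks (adjusted exact McNemar p = 0.762, 0.334, 0.0631 and 0.158).

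Ribosomal protein genes had promoter peaks far more often than other genes. An IDR summit lay within 500 bp of a TSS of 66 of the 86 ribosomal protein genes (76.7%), against 22.2% of the other protein-coding genes (odds ratio 11.4, Fisher's exact adjusted p = 2.64e-25), with the strongest peaks at RpL34b and RpS27 (signals 3176 and 2275). The share in the single replicates was 82.2% ± 6.40 (SD, n = 3). Over all protein-coding genes, 3141 of 13945 had such a peak (22.5%). The Notch pathway list had 12 of 26 genes (46.2%, Fisher's exact adjusted p = 0.0282), led by E(spl)m3-HLH, a target of Notch signalling, numb, an inhibitor of Notch, and aph-1, a gamma-secretase subunit gene. The heat shock list had 10 of 21 (47.6%, Fisher's exact adjusted p = 0.0435), led by Hsp27, the mitochondrial chaperone gene Hsc70-5 and Hsp83, with signals of 5474, 2898 and 2107. When only genes with any pooled promoter peak were taken as the background, the ribosomal protein list alone was still called (Fisher's exact adjusted p = 6.6e-08), with p of 0.902 for the Notch list and 0.770 for the heat shock list by the same test. With the 5'-most TSS alone both of the latter had an adjusted Fisher's exact p of 0.065, and among the 4730 stronger peaks the Notch list had 0.122; the heat shock list had 0.114 with 1000 bp around the TSS and 0.0564 without replicate 2. The control library was not analysed here, so open promoters were not separated from bound ones.

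Genes of the receptor, gut and cuticle, and histone lists had few promoter peaks. Of the 119 odorant and gustatory receptor genes 2 had one (1.68%, Fisher's exact adjusted p = 5.23e-10), Gr21a and Gr77a, with signals of 330.7 and 238.0. None of the 26 genes of the list named adult gut digestion and cuticle had one (Fisher's exact adjusted p = 0.00811, but 0.0753 in the 4730 stronger peaks, 0.067 in those matched in all replicates and 0.0561 without replicate 2). That list was mixed. It also held yolk protein genes such as Yp1, larval serum protein genes such as Lsp2, larval cuticle genes such as Lcp1 and the opsin gene ninaE. Among 115 histone genes, most of them near-identical repeated copies in which reads can be hard to place, 3 had one (2.61%, Fisher's exact adjusted p = 9.84e-09). These 3, His3.3B, His2Av and His3.3A, encode variant histones. Only 5 genes of the receptor list, 4 of the gut and cuticle list and 3 of the histone list had any pooled promoter peak. With only such genes as the background, none of these 3 lists was called lower, though few of their genes were left to compare.

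The other 12 lists were not called in the main test. The Polycomb and Trithorax group had 12 of 28 genes (42.9%, Fisher's exact adjusted p = 0.0521, and 0.0284 without replicate 3, which is past the threshold), with ph-p (signal 13392) and brm (5769) the strongest, and the insulator and promoter zinc finger genes 9 of 24 (37.5%), with Cp190 (7022) and M1BP (3814) the strongest. Heterochromatin protein genes had 6 of 19, led by HP4 and HP1b, germline genes 8 of 26, led by orb and Sxl, muscle genes 7 of 23, led by sls and tin, and cell cycle and replication genes 10 of 34, led by Dp and Cdk1. Oxidative phosphorylation genes had 9 of 33, led by ND-51 and blw, early neural genes 5 of 23, led by elav with a signal of 7999, and piRNA pathway genes 7 of 36, led by papi and vas. Lower values were found for genes of neuronal function, 3 of 22, with Syx1A and Shab, for segmentation and dorsoventral patterning genes, 4 of 39, with hry and rho, and for the 8 Hox genes, of which none had an IDR promoter peak. Without replicate 3 the neuronal and segmentation lists were called lower (odds ratios 0.0990 and 0.173, Fisher's exact adjusted p = 0.0461 and 0.0272), and the segmentation list was also called lower in the 4730 stronger peaks and in those matched in all replicates (Fisher's exact adjusted p = 0.0125 and 0.0461). Adjusted Fisher's exact p in these 12 lists ran from 0.0521 to 1. The cell cycle and oxidative phosphorylation shares differed most between replicates, at 58.8% and 57.6% in replicate 1, 26.5% and 36.4% in replicate 2 and 26.5% and 21.2% in replicate 3.

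**Figure D4:**
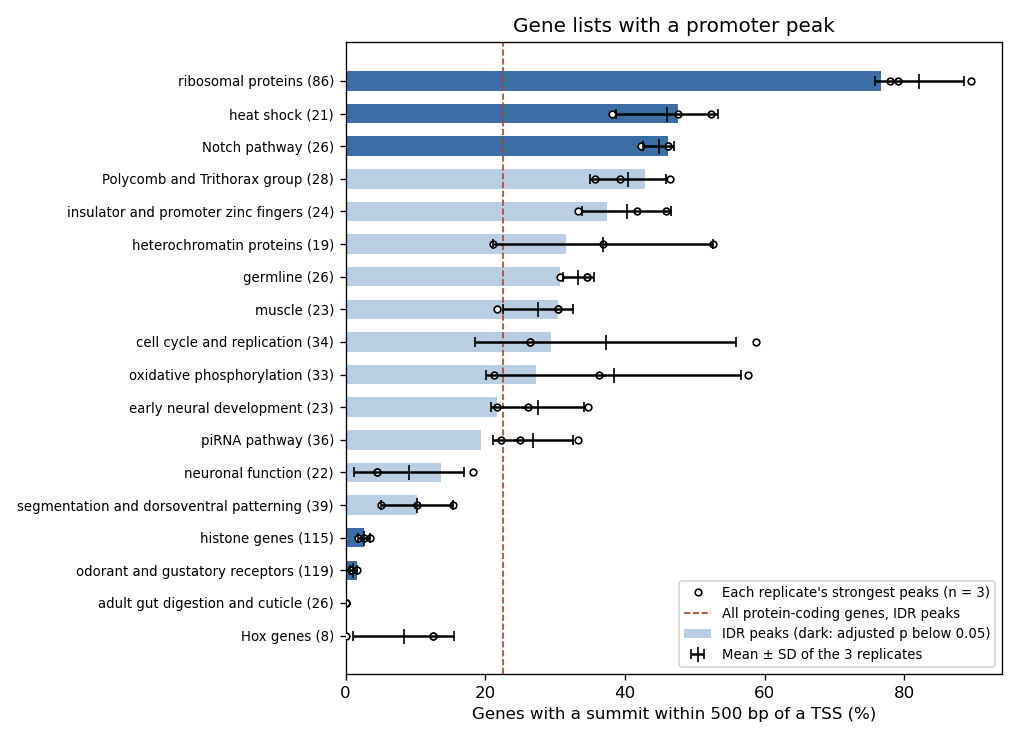
Share of the genes of each list (number of genes in brackets) with a summit within 500 bp of a TSS (%, horizontal axis), for IDR peaks (bars, dark where the adjusted p was below 0.05) and for the strongest peaks of each replicate (open circles, with mean and SD, n = 3); the dashed line is the 22.5% of all protein-coding genes. Ribosomal protein genes stand at 76.7%, and the receptor, histone, and gut and cuticle lists at 2.61% or less.

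Among gene biotypes, protein-coding genes had a promoter peak more often than all other genes (22.5% against 10.9%, Fisher's exact adjusted p = 1.97e-67). Genes of long noncoding RNAs (11.9%), antisense RNAs (12.5%), snoRNAs (9.67%), other noncoding RNAs (7.04%), miRNAs (6.92%) and pseudogenes (4.10%) had one less often, as did rRNA genes, with 0 of 99 (Fisher's exact adjusted p from 7.19e-22 to 1.89e-05). Like most of the histone genes, rRNA genes are repeated copies in which reads can be hard to place, so a lack of binding at them is not shown. snRNA genes, with 5 of 32, were not called (Fisher's exact adjusted p = 0.662, but 0.0289 for a lower share in the 4730 stronger peaks). Of 290 tRNA genes 66 had one (22.8%, Fisher's exact adjusted p = 0.230), but these peaks were mostly weak: among IDR peaks matched in all replicates tRNA genes had a peak less often than other genes, with an odds ratio of 0.400 (Fisher's exact adjusted p = 3.68e-05). The tRNA share differed between replicates, at 15.2%, 27.9% and 12.8% in replicates 1, 2 and 3.

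Peaks were spread over the euchromatic arms and were scarce in pericentromeric sequence and on chromosome 4. Pericentromeric sequence, 18.0 Mb in all, held 31 IDR summits, or 0.328%, against 13.4% of random placements, a ratio of 0.0244. Chromosome 4 held 8 summits, at 6.01 per Mb, against 77.6 to 92.0 per Mb on the euchromatic parts of 2L, 2R, 3L, 3R and X (permutation adjusted p = 0.002 for the shortages in pericentromeric sequence and on chromosome 4). In the single replicates the pericentromeric share was 0.451% ± 0.116 (SD, n = 3). The 3 strongest pericentromeric peaks were at promoters: of asRNA:CR45999 (3R, 4395107 to 4395595, signal 2553), DhpD (3R, 4229146 to 4229569, 1631) and lncRNA:CR43493 (X, 22490920 to 22491557, 1539), and 19 of the 31 were matched in all replicates. These 3 peaks all lay within 500 kb of the approximate borders. With the borders moved 500 kb towards the centromere none of the 3 was pericentromeric, and the ratio of summits to random placements was 0.0100. The pooled peaks outside the IDR set had a similarly low pericentromeric share, 0.487%, and the difference between the 2 shares did not pass the test (Fisher's exact adjusted p = 0.207). On chromosome 4 the shares of IDR and remaining pooled summits were 0.0846% and 0.102%, and their difference did not pass either (Fisher's exact adjusted p = 0.842).

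Annotated transposable elements held 26 summits, or 0.275%, against 5.75% of random placements (permutation p = 0.002). The pooled peaks outside the IDR set held 0.297% (Fisher's exact p = 0.818 between the 2 shares). Many such elements are repeated copies in which reads can be hard to place. The random placements were not limited to unique sequence here, so a lack of binding in these elements is not shown. Soft-masked bases, which include low-complexity sequence, held 24.8% against 20.1% (permutation p = 0.002), and 24.4% ± 0.571 in the single replicates (SD, n = 3). The direction of the latter depended on base composition: positions of equal GC content were soft-masked more often, at 30.5% (permutation p = 0.0198).

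Intervals of 5 piRNA source loci held 0 to 3 IDR summits each, and none was called against random intervals (permutation adjusted p = 0.525 for each); even 0 summits would have given a permutation p of 0.102 or more before adjustment, so this test could not have called a shortage. The 42AB interval, 250 kb long, held 1 IDR summit, at 6465002 of 2R within an annotated transposable element, where random intervals of its length held 15.8 on average. The 38C interval held 3 against 9.31, the flamenco interval 3 against 13.3, and the 20A and 80F intervals 0 against 3.84 and 3.89. Annotated transposable elements covered only 1.94% of the 20A interval, against 54.1% to 71.3% of the other intervals. The 20A interval may therefore miss the source locus, and its count of 0 says nothing about that locus. Of the 3 summits in the flamenco interval, 1 lay 189 bp from the annotated TSS of lncRNA:flam (X, 21631502 to 21631917, signal 1390), with ranks among all IDR peaks of 1557, and the other two lay at the promoter of DIP1.

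CG2678 itself (FBgn0014931, 3R, 7913851 to 7916550) had no peak within 10 kb in any of the 5 lists. The nearest IDR summit was 20100 bp from the gene, and 31.2% of protein-coding genes likewise had no IDR summit within 10 kb. Within 25 kb there were 2 IDR summits, against a median of 4 around protein-coding genes.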

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

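The alternatives for positions outside soft-masked sequence, for the strongest summit of each interval, for GC matching of repeats and for the CACTGT word were chosen after the results were seen; the others were planned. Of 599 alternative values over 79 results, 516 kept their direction and side of the threshold, or stayed within 1.5 times for a count; among values that kept their direction, 31 for single classes, arms, motifs, lists and biotypes were no longer past the threshold, besides those of chromosome 4 and pericentromeric sequence given below, and 7 were newly past it. Replicate matching, the promoter and coding shares, the GRGG shortage, the signal difference and the ribosomal protein list kept theirs under every alternative run. Against the remaining pooled peaks as background the ratios were 0.827 on chromosome 4 and 0.673 in pericentromeric sequence, no longer past the threshold, and 0.958 on 2L, 0.975 on 3L and 0.991 on 3R, now below 1; arm ratios above 1 follow in part from the pericentromeric shortage, as shares add to a fixed total, and the remaining pooled peaks show the same shortage themselves. Against the weakest pooled peaks the intron ratio was 0.872 and that of other exons 0.849. With GC-matched positions the ratios were 0.813 for soft-masked sequence, 1.00 for 5' UTRs, 1.08 for GAGAG, 1.12 for CAGCTG, 1.05 for ACACAC, 1.02 for TCAGTT, 2.19 for CGCGCG and 1.00 for AAAAAA, each on the other side of 1, and the counts of 6-bp words were 206 and 360. At summits with no soft-masked base within 50 bp the ratios turned to 1.68 for CAGGTA, 1.02 for TCAGTT and 0.652 for AAAAAA; soft-masking removes A runs by construction. The number of gene lists called higher was 1 with the 5'-most TSS and 1 with a background of genes with a pooled promoter peak, where 0 were called lower and the histone odds ratio was 3.60 with few genes left. Leaving out each replicate gave 2 to 5 lists called lower, with 5 without replicate 3. The tRNA odds ratio fell below 1, to 0.376 in the 4730 stronger peaks, 0.400 in peaks matched in all replicates and 0.407 to 0.617 without each replicate. Odds ratios of lists that were never called also crossed 1: to 1.196 for piRNA pathway and 0.652 for early neural genes in the 4730 stronger peaks, 1.36 for piRNA pathway and 0.910 for muscle genes in peaks matched in all replicates, 1.13 to 1.26 for piRNA pathway genes without each replicate, 0.820 to 2.03 for muscle genes likewise, 1.25 for piRNA pathway genes within 1000 bp of a TSS, and, with a pooled promoter peak required, 0.982 for cell cycle, 0.628 for early neural, 0.592 for muscle, 0.650 for oxidative phosphorylation and 2.58 for piRNA pathway genes. At 25 kb, 2 peaks lay near the tagged gene. Except where said, the cause was not tested. Read depth is not given, so weak sites absent from the lists cannot be called unbound.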

Other observations

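The protein-coding gene holding the most IDR summits was kirre, a cell adhesion gene of muscle founder cells (X, 2740384 to 3134532), with 48 over 394.1 kb. Next came CG1677 with 26, shn, a zinc finger gene of Dpp signalling, and the teneurin gene Ten-a with 24 each, and bun, the nuclear receptor gene Eip75B and rdx with 22 each. These 7 were named after their values were seen, as the genes with 22 summits or more; the numbers were not corrected for gene length, and no test was run on them.

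In what follows, the tests of the weakest pooled peaks, of summits far from a TSS, of both arrangements of the word CACTGT (with the window searched) and of the weakest peaks in pericentromeric sequence were chosen after the results were seen. The design has 1 group, so no biological explanation was tested.

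The AT-rich, GRGG-poor centre of the IDR peaks was not shared by every called peak, since the weakest pooled peaks differed from their flanks by 0.233 percentage points of GC content (95% interval -0.00431 to 0.470), nor was it that of promoters, since summits more than 500 bp from a TSS differed by -12.2 percentage points. The pooled list reached down to a −log10 q-value of 0.350, so its weakest peaks may lie near background. They therefore cannot exclude an effect of the procedure that grows with signal. Preferential recovery of AT-rich fragments would place peaks at AT-rich positions in general. Random positions of the same GC content lay within 100 bp of a pooled summit 1.24 times as often as other positions (5.60% against 4.51%). Near an IDR summit they lay 1.66 times as often. Most pooled peaks were outside the IDR set, and the weakest lacked the AT-rich centre, so the pooled ratio says little about the IDR peaks. The IDR peaks were AT-rich themselves, so their ratio cannot tell recovery from a sequence preference. Preferential recovery therefore remains open. Low-complexity sequence also remains open. At the 2423 summits with no soft-masked base within 50 bp the difference shrank to -4.09 percentage points (95% interval -4.59 to -3.60), and masking itself selects AT-rich sequence, so the part that may come from low-complexity sequence cannot be told apart from a sequence preference.

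A word search also showed CACTGT pointing away from the summit on its flanks, as ACAGTG to the left and CACTGT to the right. Between 50 and 120 bp from the summit, 880 IDR peaks (9.30%) had the outward arrangement and 382 (4.04%) the inward one, a ratio of 2.30 (exact McNemar p = 2.5e-47), and 163 against 7 had it on both sides; in the replicates' own strongest peaks the shares were 9.20% ± 0.142 and 4.15% ± 0.125 (SD, n = 3). Both arrangements have the same GC content, so GC content alone would leave the ratio near that at GC-matched positions, 1.25. It was 1.31 at the weakest pooled peaks and 3.60 at the 1000 strongest. A difference in base composition between the strands on either side of the summit could favour an arrangement and was not tested. With words in soft-masked bases and annotated transposable elements not counted, 829 summits had the outward and 338 the inward arrangement (ratio 2.45, exact McNemar p = 1.47e-49). At the 9356 summits in unique sequence 872 and 374 did (ratio 2.33). These filters dropped only 7.26% of the summits with either arrangement and 103 of all 9459 summits, so few of them lay in such repeats. The values argue against masked, annotated or exact repeat copies as the source of the arrangement. Diverged copies that are neither masked nor annotated were not tested. A window ending 5 bp further out was tried first, and its ratios were 2.25 over all summits and 2.27 in unique sequence. The word was found in these same peaks, and no independent test was run.

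The shortage of pericentromeric peaks was not removed by counting only positions whose surrounding 36 bp occur once in the arms. These were 43.3% of pericentromeric bases, and the ratio of summits to random positions was then 0.0491; on chromosome 4 it was 0.0882. The shortage was shared by the weakest pooled peaks, with a ratio of 0.0404, so it may reflect what the whole list has in common, such as peak calling against the control or open chromatin, rather than the strongest sites alone. The read length and the handling of reads with several matches are not given in the sources used here.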
